A study of Mus musculus with 12 samples.

How the data were processed

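The data are 12 RNA-seq libraries of mouse (Mus musculus) neutrophils sorted from the left ventricle, 6 with the genotype label control (numbered 2, 6, 7, 8, 11 and 12 in the titles) and 6 with the genotype label LOY (3, 4, 5, 10, 14 and 15). All 12 titles name control transplants and all treatment labels read control, so groups were taken from the genotype label. Per the labels' protocols, hearts were digested with collagenases, hyaluronidase and DNase, 800 cells per library were sorted, and cDNA was made and amplified with the SMART-Seq v4 ultra low input kit before Nextera XT libraries were prepared. This chemistry carries neither strand nor molecular identifiers, so overlapping and antisense genes share reads, and PCR copies count as reads. Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2, and the builds named are GRCm38 and mm10.

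The authors deposited 1 table of 11911 genes with an Ensembl identifier and a symbol each. Its signal columns hold, per the file headers and the values, read counts per gene that the authors divided by 1 factor per library. Every value above 0 was a whole multiple of 1 step per library (100% within 0.01 of a read), which gave the reads and the factors back. The authors' table also gives a log2 fold change, LOY over control by its sign in the values, and a p-value with its adjusted p-value per gene; 9722 genes have a p-value and 2189 do not. The tool behind the authors' scaling and test is not given in the sources used here. A DESeq2 run on the recovered reads gave the same library factors (largest relative difference 1.07e-10), and all 303 calls were shared. Genes of low mean are not in the table, so the totals per library are totals of the listed genes. Symbols that a spreadsheet had turned into dates (17 genes) or that were blank (8 genes) were replaced by those of GENCODE M21, which is on GRCm38; 11896 identifiers matched it, and coordinates are from it.

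The total reads of the listed genes ran from 6767108 to 12561174 per library. Intervals and floors cover counting error only. A gene with 0 reads in a group was set against a floor of 3 reads over that group, and 95% Clopper-Pearson intervals were used for ratios of reads.

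The main test was limma 3.58.1 with a trend and robust empirical Bayes on log2(normalised reads + 1), with an intercept and the genotype, all 12 libraries, and genes of at least 10 normalised reads in at least 6 libraries (6951 genes). Adjusted p-values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Fold changes are differences of group means of log2(value + 1), so for a gene at or near 0 in some libraries they can be far from the fold of the mean reads, in either direction. The 27 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 2 tested genes, and again with an estimated correlation and with fry. The Y-linked call alone held with an estimated correlation (adjusted p = 0.00717). Marker list means per library were compared by exact permutation over all assignments of the 12 libraries. No replicate number is shared between the groups, so no paired fit was made. No 2 libraries agreed within sampling noise (the lowest chi-square per degree of freedom of a pair was 177). Before the data were examined, the tests, lists, alternatives and the rule for named genes were fixed. The rule names every measured Y-linked gene and X relative, and up to 10 genes per direction past the threshold. Where fewer pass, it fills up to 5 per direction by unadjusted p, and Y-linked genes are left out of both. It also names 2 to 4 members of smallest p of each list described. In part of the lists, the members given with values are among the 4 of smallest p but leave out some of smaller p. Genes with only a serial identifier were passed over.

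Alternatives were DESeq2 1.42.0 on the recovered reads, quantile normalization, no filter (a value above 0 in at least 1 library), a mean of at least 50, array weights, pseudocounts of 0.5 and 5, a log2 fold change of at least 1, removal of the Y-linked list, and each library left out in turn. The fixed design named edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) on the recovered reads as an alternative to add. Chosen after seeing the data were a fit without the library of lowest array weight in each group (control 8 and LOY 5) and a fit with the cardiomyocyte list mean as a covariate. The filters, array weights, pseudocounts and removal of the Y-linked list were fixed in advance for the genome-wide count, and were applied to the gene lists and, except for that removal, to the Y-linked count as additions.

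The fit was tested on simulated counts drawn with the means, sizes and dispersion of these libraries, with the highest dispersions capped. Each gene was drawn independently, and changed genes were picked from those past the value filter in the real data. Percentages are shares of the changed genes that were tested in the simulation. For LOY against control, with 6982 genes tested, it recovered 0% of genes changed 2-fold, 6.98% of those changed 4-fold, 17.9% of those changed 8-fold and 33.3% of those changed 16-fold, and called 2 of 6810 unchanged genes. With a dispersion of 0.1 and 11508 genes tested it recovered 62% of genes changed 2-fold and 100% of those changed 4-fold. R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.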

Results

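RNA was sequenced from neutrophils sorted out of mouse hearts, in 6 libraries of the control genotype and 6 of the genotype labelled LOY, which the series title ties to loss of the Y chromosome in blood-forming cells. Each library came from 800 cells of the left ventricle, sorted by flow cytometry as positive for the leukocyte allele CD45.2, the neutrophil surface protein Ly6G and a red fluorescent protein, and negative for the macrophage receptor CD64. The titles call the mice recipients of a bone marrow transplant, and the treatment label reads control in all 12. Values are the reads per gene divided by 1 factor per library, called normalised reads here. The table lists 11911 genes. The reads recovered from it came to 9937692 ± 1846231 per control library and 8364132 ± 1408963 per LOY library (SD, n = 6 each), with a range of 6767108 to 12561174. Between 7539 and 9463 genes were above 0 in a library, while 4123 genes were above 0 in all 12 libraries and 3367 (28.3%) in 6 or fewer. The most abundant transcript was Il1b, the inflammatory cytokine interleukin-1 beta, with 239921 ± 99812 normalised reads in the control libraries and 204708 ± 76989 in the LOY libraries (SD, n = 6 each). The labels number the libraries and do not say that each came from a separate mouse, so p-values measure the spread between these libraries. The sex of the recipients is not given in the sources used here.

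The first comparison asked whether transcripts of the Y-linked list were missing from the LOY libraries, and those of the table were nearly absent. The 3 genes of the Y-linked list that the table holds, Ddx3y, Eif2s3y and Uty, summed to 1455 ± 354 normalised reads in the control libraries and to 12.9 ± 23.9 in the LOY libraries (SD, n = 6 each). The lowest control library stood at 1032 and the highest LOY library at 59.3, and 4 of the 6 LOY libraries had 0 reads of all 3 genes. The log2 sums did not overlap (two-sided exact permutation test, p = 0.00216, the smallest that 6 libraries against 6 can give).

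Ddx3y, a DEAD-box RNA helicase (ENSMUSG00000069045, GRCm38 chromosome Y, 1260771 to 1286629), had 857 ± 422 normalised reads in the control libraries and 8.77 ± 20.97 in the LOY libraries (SD, n = 6 each). Its log2 fold change was -8.46 (SE 1.22), with an adjusted p of 0.0197 in limma. Of its 74 reads in the LOY group, nearly all came from LOY 10, at 51.6 normalised reads, and the rest from LOY 14, at 1.05. Eif2s3y, a subunit of translation initiation factor 2 (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847), had 542 ± 399 normalised reads in the control libraries and 4.10 ± 6.96 in the LOY libraries (SD, n = 6 each). Its log2 fold change of -6.42 (SE 1.65) missed the threshold over all genes (adjusted p = 0.708) and passed when adjusted over the list alone (adjusted p = 0.00158). Control 7 held 0.828 normalised reads of it against 87.9 to 951 in the other 5 control libraries. Uty, a relative of Kdm6a (ENSMUSG00000068457, chromosome Y, 1096861 to 1245759), was read in 4 control libraries. It had 369 reads in all there, 322 of them in control 12, and 0 reads in every LOY library. Against a floor of 3 reads over the LOY group it was at least 108-fold lower, a bound that rests mainly on control 12; it was above the value filter in only 3 libraries and was not tested. Gm4017, a processed pseudogene that lies inside the Ddx3y locus (1268548 to 1268885), had 102 ± 115 against 4.38 ± 3.71 normalised reads, and because of the overlap its reads and those of Ddx3y are uncertain in their assignment. The overlap does not account for its 2, 4 and 8 reads in LOY 3, 4 and 5, where Ddx3y had 0. The origin of those reads was not tested. The other 6 genes of the list are not listed in the table.

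**Figure D1:**
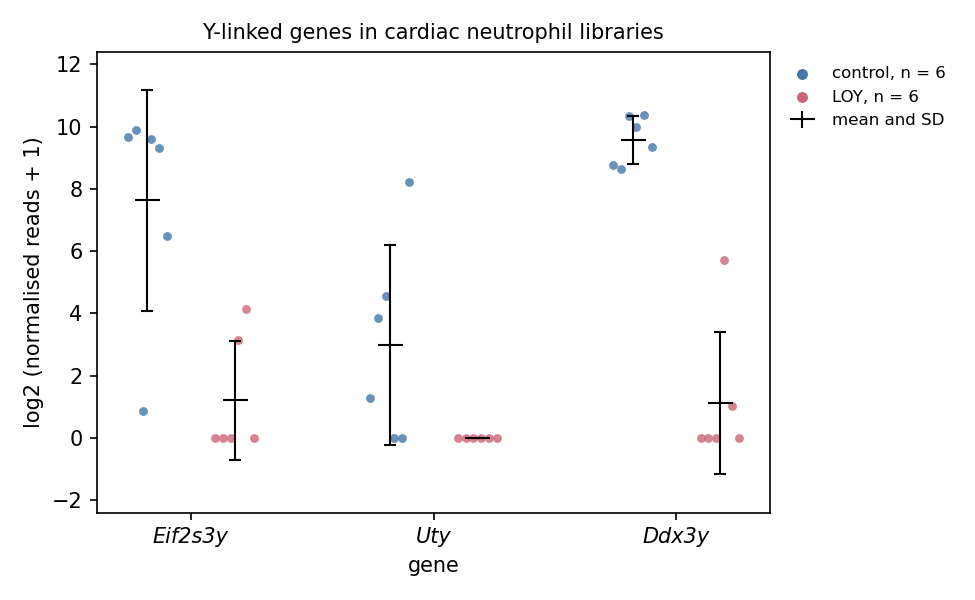
Normalised reads of the 3 Y-linked genes on a log2 (value + 1) axis, 1 point per library, 6 control (blue) and 6 LOY (red), with mean and SD in black. Ddx3y lies between 400 and 1341 normalised reads in the control libraries, and 4 of the 6 LOY libraries are at 0 for all 3 genes.

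The genome-wide comparison of LOY with control libraries found 2 genes past an adjusted p of 0.05 among 6951 tested with limma, 1 higher and 1 lower in LOY. The lower gene was Ddx3y and the higher gene was Acbd4, which encodes an acyl-CoA binding domain protein (ENSMUSG00000056938, chromosome 11, 103101682 to 103112200). Acbd4 was read in all 6 LOY libraries, at 256 ± 169 normalised reads (SD, n = 6), while the control libraries held 3 reads in all, each from control 2. The ratio was 661 (95% Clopper-Pearson interval 226 to 3210, counting error only), the log2 fold change 7.43 (SE 0.996) and the adjusted p 0.0163. The next genes, with the Y-linked list left out, did not pass in limma. On the higher side they were Zpr1, a zinc finger protein (log2 fold change 7.24, adjusted p = 0.218), and Cct4, a subunit of the chaperonin that folds actin and tubulin (5.92), Pi4kb, a phosphatidylinositol 4-kinase (5.96), and the caveolar coat gene Cavin3 (5.87), all 3 at an adjusted p of 0.696. Each of these 4 was read at 10 or more in all 6 LOY libraries and in 1 or 2 control libraries. On the lower side stood Atg3, an enzyme of autophagosome formation, with 6896 ± 1543 normalised reads in the control and 3119 ± 1250 in the LOY libraries (SD, n = 6 each; log2 fold change -1.22, SE 0.28), the zinc finger gene Zfp821 (-6.71) and Oas1c of the oligoadenylate synthetase family (-5.61), all 3 at an adjusted p of 0.696. Avl9 (-5.27, adjusted p = 0.813) and the X-linked zinc finger gene Zfx (-4.55, adjusted p = 0.857) followed. In all, 304 genes had an unadjusted p below 0.05, 162 higher and 142 lower, where chance gives 348. edgeR on the recovered reads called 0 of 7054 genes, with 129 at an unadjusted p below 0.05. It gave Ddx3y a log2 fold change of -6.60 at an adjusted p of 0.9998, so its count of 0 says little about other genes. DESeq2 on the same reads called 303, with Atg3 (adjusted p = 0.0158), Avl9 (1.88e-05) and Zfx (0.00916) among them. Under other splits of the 12 libraries into 6 and 6, DESeq2 called 228 to 343 genes. In the authors' deposited table Cct4, Pi4kb, Cavin3 and Oas1c have adjusted p-values of 0.155 to 0.605, and Zpr1 and Zfp821 have none. In fits without a LOY library, Acbd4 fell below the filter of 6 libraries, so it was not tested and had no way to pass. With control 7, 8 or 12 or LOY 3, 4, 5, 14 or 15 left out, 0 genes passed in limma. Without control 2 it was 1, without control 6 it was 3 and included Zpr1 (adjusted p = 0.0136), without control 11 it was 4 and included Cct4 (0.0417), and without LOY 10 it was 2, Ddx3y and Zfp821 (0.00742).

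**Figure D2:**
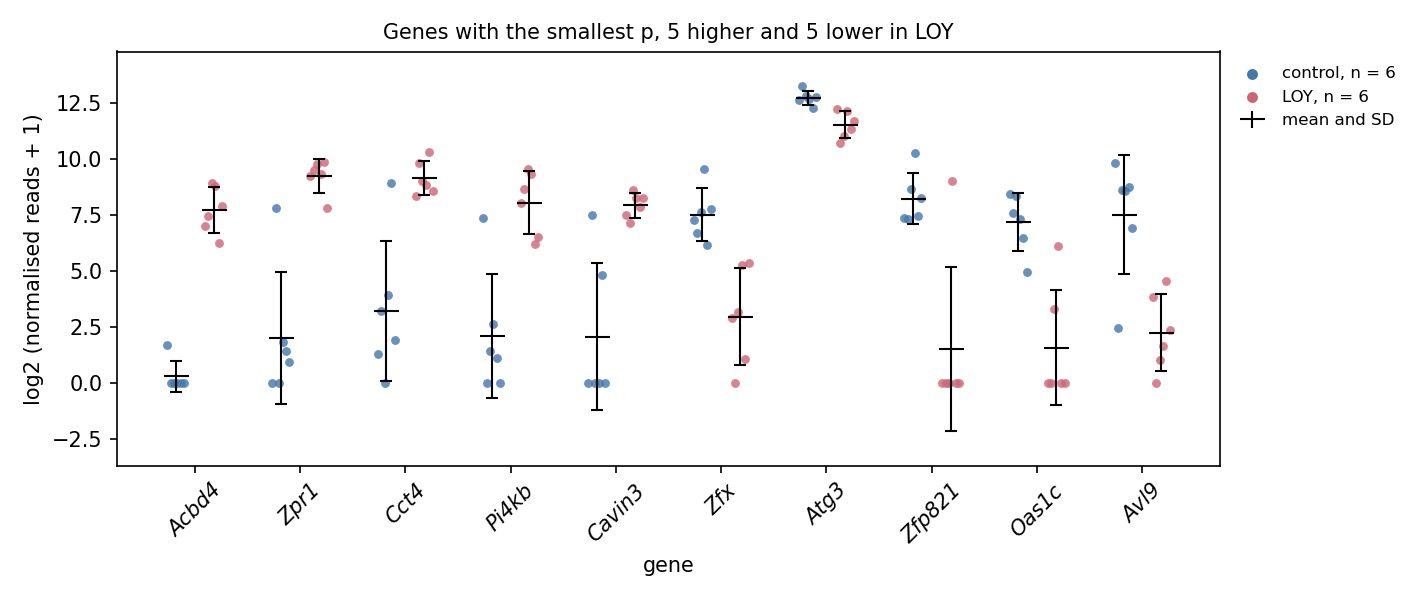
Normalised reads of the 5 genes with the smallest p among those higher in LOY and the 5 among those lower, with the Y-linked list left out, on a log2 (value + 1) axis, 1 point per library with mean and SD in black. Of these 10 genes, Acbd4 alone passed the adjusted threshold in limma, and its 6 LOY libraries all lie above its 6 control libraries.

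The X chromosome carries relatives of the Y-linked genes, and their level was compared next. All 7 were tested and none passed over all genes in limma, with a mean log2 fold change of -0.84 and a median of -0.06 (camera adjusted p = 0.451). Ddx3x, the relative of Ddx3y, was read in every library, at 2147 ± 576 normalised reads in the control and 2430 ± 935 in the LOY libraries (SD, n = 6 each), and its log2 fold change of 0.13 had a 95% interval of -0.55 to 0.80. Zfx had 247 ± 252 normalised reads in the control and 15.4 ± 18.2 in the LOY libraries (SD, n = 6 each). It was past the threshold in limma when adjusted over the list alone (adjusted p = 0.0165), and DESeq2 called it over all genes (adjusted p = 0.00916). The log2 fold changes of the other 5 were -1.78 for Eif2s3x, -0.34 for Uba1, -0.060 for Usp9x, 0.056 for Kdm5c and 0.68 for Kdm6a, with standard errors of 1.73, 0.998, 1.76, 1.51 and 1.84. Their 95% intervals include a 2-fold change either way, and the sign of Kdm5c and of Usp9x turned with another pseudocount.

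None of the 21 tested genes that mark mature neutrophils passed. S100a9, a calcium-binding protein that fills the neutrophil cytosol, had 132105 ± 68717 normalised reads in the control and 95152 ± 34171 in the LOY libraries (SD, n = 6 each; log2 fold change -0.42, SE 0.32). The chemokine receptor gene Cxcr2 had 14166 ± 4192 and 11463 ± 4567 (log2 fold change -0.34, SE 0.26), Wfdc17 a log2 fold change of -0.73 (SE 0.47), and Ly6g itself, the gene of the sorting antigen, -2.66 (SE 1.98). It had 0 to 5.82 normalised reads in LOY 3, 4 and 10 and 0.925 in control 12, against 186 to 1039 in the other 8 libraries. The log2 fold change was negative for 16 of the 21 genes and positive for 5 (camera adjusted p = 0.658). For 12 of the 21, Csf3r, Cxcr2 and Retnlg among them, the 95% interval lay within 1 log2 unit of 0. Granule genes did not pass either. Of 12 tested genes of the secondary and tertiary granules, 8 had a negative log2 fold change (camera adjusted p = 0.658), with Lcn2 at 5226 ± 1629 in the control and 4088 ± 1564 in the LOY libraries (SD, n = 6 each) and Ceacam1 at a log2 fold change of -0.77 (SE 0.65). In the primary granule list only Cst7 and Srgn were tested, with log2 fold changes of -1.05 (SE 1.22) and -0.12 (SE 0.28) and a camera adjusted p of 0.658.

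Inflammatory, interferon and fibrosis-related genes were compared as lists fixed in advance, and none of their members passed over all genes or over a list alone. Of 23 tested cytokine and NF-kB genes, 15 had a negative log2 fold change (mean -0.33, camera adjusted p = 0.658). Il18 stood at a log2 fold change of -2.78 (SE 1.80). The inflammasome gene Nlrp3 had 2742 ± 1241 normalised reads in the control and 2029 ± 952 in the LOY libraries (SD, n = 6 each). The chemokine gene Ccl3 had 4228 ± 1318 and 6412 ± 3807 (SD, n = 6 each). Of 26 interferon-stimulated genes, 15 were negative and 11 positive (mean -0.27, camera adjusted p = 0.743), with Ddx58, a sensor of viral RNA, at 1.42 (SE 0.66) and the GTPase gene Ifi47 at -3.57 (SE 1.70). The TGF-beta and profibrotic list, 19 genes tested, had 10 positive and 9 negative values (mean 0.12, camera adjusted p = 0.743). Within it the inhibitors of differentiation Id1 and Id3 stood at log2 fold changes of 2.59 (SE 1.43) and -3.01 (SE 1.74), and the receptor gene Tgfbr2 had 950 ± 695 against 383 ± 339 normalised reads (SD, n = 6 each). The list of tissue-aged neutrophil genes had 12 of 18 positive values (mean 0.072, median 0.39, camera adjusted p = 0.658), with Nfkb1 at 1.11 (SE 0.59) and Xbp1 at -0.60 (SE 0.39). Of 17 migration and adhesion genes 11 were positive (mean 0.14, camera adjusted p = 0.743), Pecam1 at 1.70 (SE 1.23) and Fpr2 at -0.55 (SE 0.44) among those of smallest p.

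Of the remaining lists of cell programs, no gene passed over all genes or over a list alone. Of 12 oxidative burst genes 6 were positive and 6 negative, with a mean of 0.047 and a median of -0.029 (camera adjusted p = 0.880). Sod2 stood at 1.73 (SE 1.26) and Cat at -1.61 (SE 1.95). The NADPH oxidase subunit gene Cyba had 7477 ± 1894 normalised reads in the control and 9055 ± 4441 in the LOY libraries (SD, n = 6 each). For 8 of the 12 the 95% interval lay within 1 log2 unit of 0. Of 22 glycolysis and hypoxia genes 12 were positive (mean 0.062, camera adjusted p = 0.894). Pfkl stood at 2.41 (SE 1.23), Pkm at -0.35 (SE 0.20) and Slc2a1 at -0.81 (SE 0.51). The 13 genes encoded by mitochondrial DNA were negative in 12 cases (mean -0.25, camera adjusted p = 0.451, and 0.0340 without LOY 15), mt-Nd5 at -0.43 (SE 0.33) and mt-Nd2 at -0.36 (SE 0.38). With an estimated correlation the adjusted p of this list was 0.879 over all libraries. Of 13 p53 target genes 7 were negative (mean -0.25, camera adjusted p = 0.743), with Sesn2 at -0.87 (SE 0.54) and Mdm2 at 0.45 (SE 0.49). Only 3 cell cycle genes were tested, Pcna at 1.77 (SE 1.12), Top2a at 1.94 (SE 1.70) and Mki67 at -1.44 (SE 1.71), with a mean of 0.755 and a camera adjusted p of 0.658. Among 18 genes of apoptosis and survival (mean 0.24, camera adjusted p = 0.880), the caspase-8 inhibitor Cflar stood at -1.54 (SE 0.56), the inhibitor of apoptosis Birc3 at 1.12 (SE 0.46) and Bad at 2.98 (SE 1.32). Of 15 genes of class I antigen presentation 9 were positive (mean 0.14, camera adjusted p = 0.743), with H2-Q7 at 1.28 (SE 0.54) and Tap1 at 0.70 (SE 0.55). Of 20 stress and immediate early genes, which can mark handling of the tissue, 13 were positive (mean 0.11, camera adjusted p = 0.667), Hsp90aa1 at 0.79 (SE 0.45) and Klf2 at -0.89 (SE 0.55).

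**Figure D3:**
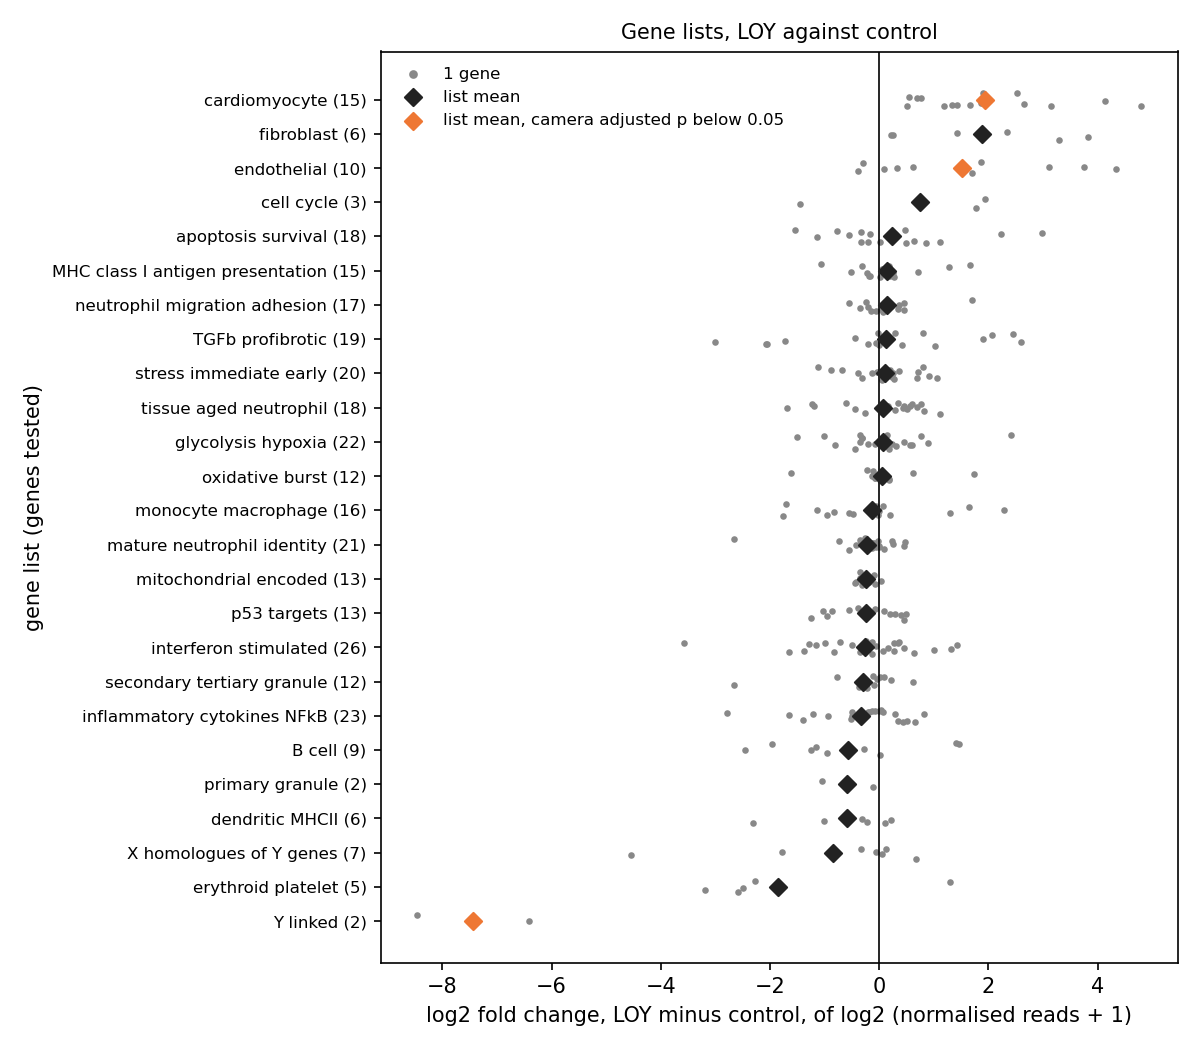
Log2 fold changes, LOY minus control, of the tested genes of each list (grey points) with the list mean as a diamond, orange where the camera adjusted p lay below 0.05. Most neutrophil lists centre near 0, the Y-linked list mean is -7.44 and the cardiomyocyte list mean 1.94.

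At the preset correlation camera called the list of heart muscle markers higher in the LOY libraries, in cells sorted for Ly6G. All 15 genes of the cardiomyocyte list were tested and all 15 had a positive log2 fold change, with a mean of 1.94 (camera adjusted p = 3.80e-06). With a correlation estimated from the data the list lost the call, at an adjusted p of 0.406, and no member passed over all genes. The cardiac myosin gene Myh6 had 397 ± 180 normalised reads in the control and 3256 ± 3595 in the LOY libraries (SD, n = 6 each; log2 fold change 2.53, SE 0.63), and the sarcomere gene Ttn had 314 ± 234 and 3136 ± 3909 (log2 fold change 2.66, SE 0.84). These 2 of the 15 passed when adjusted over the list alone (adjusted p = 0.0180 and 0.0497). The cardiac actin gene Actc1 stood at 1.67 (SE 0.61) and the natriuretic peptide gene Nppa at 4.13 (SE 1.65). LOY 10 was highest, with 10327 normalised reads of Myh6 and 10964 of Ttn, while LOY 5 held 530 and 129.

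The endothelial list was called higher as well, with 8 of 10 tested genes positive and a mean of 1.51 (camera adjusted p = 0.0428, and adjusted p = 0.406 with an estimated correlation). Cav1, the main caveolar protein gene, had 67.8 ± 68.4 normalised reads in the control and 454 ± 252 in the LOY libraries (SD, n = 6 each; log2 fold change 4.33, SE 1.43), and Egfl7 a log2 fold change of 3.11 (SE 1.31). Pecam1, which the migration list shares, was among the positive members. With 1 library left out at a time, the camera call stood only without control 11 (adjusted p = 0.0304) or LOY 5 (adjusted p = 0.000997). The Y-linked list entered the adjustment in only 6 of these 12 fits, since Eif2s3y fell below the filter in the others. Removal of the Y-linked list alone moved the endothelial camera adjusted p to 0.0610 at the same list mean. Some of these losses can thus come from the adjustment over lists. All 6 tested fibroblast markers were positive, with a mean of 1.89, and the list missed the threshold (camera adjusted p = 0.0714; 0.406 with an estimated correlation, and 0.0121 with no filter, a setting added after the plan), with Dcn at 277 ± 284 against 1102 ± 837 normalised reads and Postn at 48.4 ± 52.5 against 684 ± 799 (SD, n = 6 each). No tested list for a blood cell type passed. The list mean was -0.14 over 16 macrophage genes (camera adjusted p = 0.667; Adgre1 -1.76, Fcgr1 2.28), -0.59 over 6 dendritic and MHC class II genes (0.667; Ciita -2.31, H2-Aa -1.005), -0.58 over 9 B cell genes (0.607; Ighd -0.96, Ebf1 -2.46) and -1.85 over 5 red cell and platelet genes (0.451, and 0.0104 without control 11; Hbb-bs -3.18, Hba-a1 -2.58). With an estimated correlation the adjusted p of the red cell and platelet list was 0.879 over all libraries. No gene of the lists for T and NK cells or for eosinophils, mast cells and basophils reached the value filter.

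The mean log2 level of each marker list was also compared per library, with an exact two-sided permutation test and adjustment over 9 lists. The cardiomyocyte mean was 6.80 ± 0.73 in the control and 8.74 ± 2.01 in the LOY libraries (SD, n = 6 each; exact p = 0.0541, adjusted p = 0.182), with 4 of the 6 LOY libraries above the highest control library and LOY 5, at 5.52, below the lowest, at 6.15. The endothelial mean was 4.92 ± 1.26 against 6.60 ± 1.33 (exact p = 0.0498, adjusted p = 0.182; 5 of 6 LOY libraries above the highest control) and the fibroblast mean 3.47 ± 0.87 against 5.13 ± 1.72 (exact p = 0.0606, adjusted p = 0.182; 3 of 6). For the macrophage, dendritic, B cell, T and NK cell, eosinophil, mast cell and basophil, and red cell and platelet lists the exact p lay between 0.320 and 0.786. No list differed between the groups by more than the spread between libraries after adjustment.

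**Figure D4:**
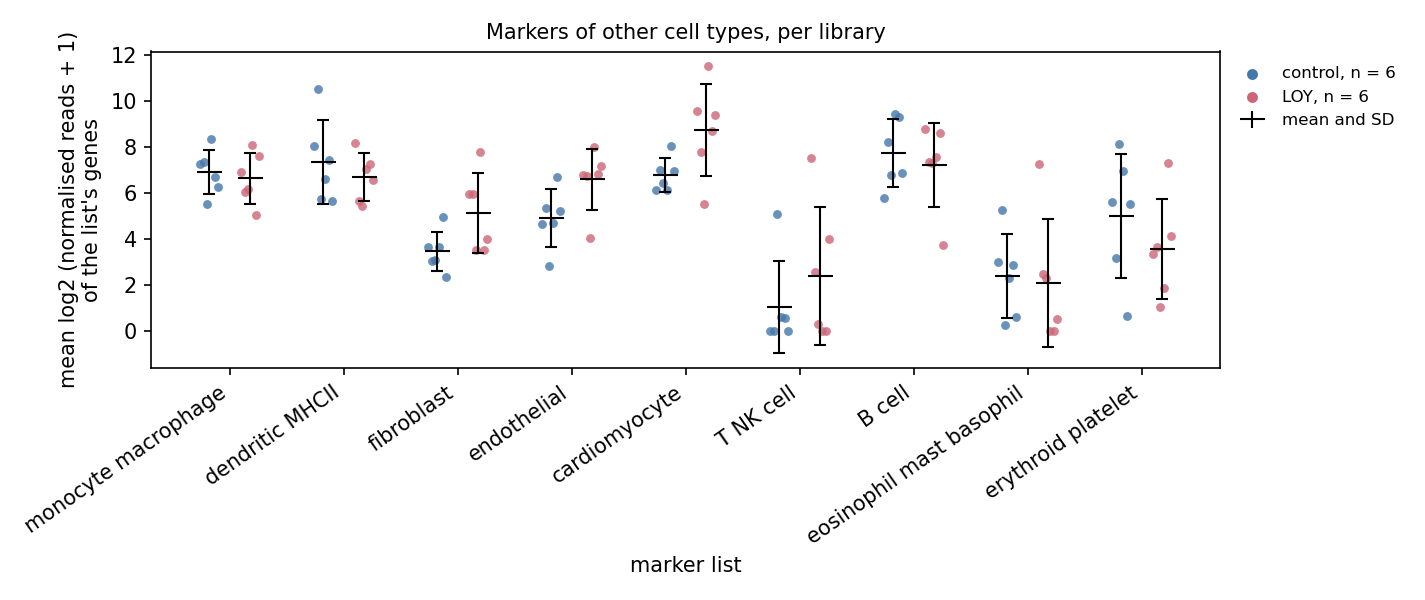
Mean log2 (normalised reads + 1) of the genes of 9 marker lists of other cell types, 1 point per library, 6 control (blue) and 6 LOY (red), with mean and SD in black. The cardiomyocyte, endothelial and fibroblast means are higher in most LOY libraries, and LOY 5 lies lowest of its group for the cardiomyocyte, endothelial and fibroblast lists.

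The authors' deposited table marks 303 genes at an adjusted p below 0.05, 186 higher and 117 lower in LOY. In the authors' deposited table Ddx3y has a log2 fold change of -6.60 and Eif2s3y of -7.05, both among the 303. Myh6 (3.04), Ttn (3.32) and Actc1 (2.35) are among the 186, and Atg3 (-1.14), Avl9 (-5.68) and Zfx (-4.00) among the 117. Of these 303 genes, 208 (68.6%) were above 0 in 6 or fewer libraries, against 15.8% of all genes that have an adjusted p there. A full separation of the 6 LOY from the 6 control libraries was seen for 10 of the 303. Only 23 of the 303 reached the value filter of the limma test, and 2 passed it.

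The libraries varied widely within each genotype. Pearson correlations of log2 values across the tested genes ran from 0.416 to 0.559 over the 66 pairs of libraries, with a median of 0.477 within and 0.482 between the groups, so libraries of 1 genotype were no closer to each other than to the other genotype. The first 2 principal components held 12.9% and 12.2% of the variance and were set mainly by control 8 and LOY 5. The median residual SD was 1.25 log2 units for 4035 tested genes above 0 in all 12 libraries and 3.37 for the other 2916. The 95% interval of the fold change lay within 1 log2 unit of 0 for 395 genes (5.68%), so a 2-fold change was not detectable for most genes with these libraries. Full separation of the genotypes was seen for 14 tested genes, where chance gives 15.0. Reads of mitochondrial genes made up 10.6 ± 4.1% in the control and 9.27 ± 4.11% in the LOY libraries (SD, n = 6 each; exact permutation p = 0.589, adjusted p = 0.667 over 5 library measures), and total reads gave an exact permutation p of 0.128 (adjusted p = 0.639).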

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

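The test of splits for Acbd4 and that of its neighbours were both set down before their results were seen. Of 65 groups of 6 libraries examined, 11 held a library whose distance from the others was large against the range of its group, where chance gives about 3.25. Many of these genes are at 0 in most libraries of a group, so that any library with reads stands apart.

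Acbd4 in control 2 had a log2 (value + 1) of 1.67, from 3 reads, while the other 5 control libraries were at 0 and all 6 LOY libraries were read. Reads taken from a neighbour stay open in part. Of the 2 genes of the table within 10 kb, 0 were higher in LOY at an unadjusted p below 0.05. Plcd3, at 0 in all control libraries and above 0 in 3 LOY libraries, was below the filter. Its exact permutation p was 0.182, the smallest that 3 libraries with reads can give. Acbd4 had 74.6 to 488 normalised reads in all 6 LOY libraries, also in those with Plcd3 at 0. In those libraries the values argue against Plcd3 as the source. Hexim1 had 412 normalised reads in the control and 206 in the LOY libraries. Chance stays open, since 359 splits of the 12 libraries into 6 and 6 (77.7% of all, the real one included) had at least 1 gene outside chromosome Y at 10 or more in every library of one side and below 10 in every library of the other. The real split had 1 such gene and the highest of the other splits had 9. Acbd4 went beyond this rule, with a lowest LOY value of 74.6 and a highest control value of 2.18. How often a split gives a gene with so wide a gap was not counted. An effect of the LOY genotype on Acbd4 was not tested apart from this and stays open.

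Ddx3y in LOY 10 had a log2 (value + 1) of 5.72, while the other LOY libraries lay between 0 and 1.04. LOY 10 was also the library with the highest cardiomyocyte list mean, at 11.5. LOY 3 and LOY 15 came next, at 9.55 and 9.41, and held 0 reads of the Y-linked list. LOY 14, at 8.68, held 17, while LOY 4 and LOY 5, lowest at 7.77 and 5.52, held 0. The origin of the Y-linked reads in LOY 10 and LOY 14 was not tested, and the sex of the transplant recipients is not given in the sources used here. Kdm5c in control 6 was at 1.32, while the other control libraries lay between 7.36 and 9.54.

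Zpr1 had a log2 value of 7.77 in control 6, above the 0 to 1.82 of the other control libraries, and of 7.79 in LOY 15, below the 9.21 to 9.84 of the other LOY libraries. Pi4kb in control 2 was at 7.34, above 0 to 2.60 in the others, and Zfp821 in LOY 10 was at 8.98 with the other 5 LOY libraries at 0.

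Among the marker lists of other cell types, the endothelial mean of LOY 5 was 4.06, below the 6.74 to 7.98 of the other LOY libraries. The B cell mean of LOY 15 was 3.75, below 7.30 to 8.77. The mean of the T and NK cell list was 5.09 in control 7, above 0 to 0.607 in the other control libraries, and the mean of the list for eosinophils, mast cells and basophils was 7.26 in LOY 3, above 0 to 2.49; in each of these 2 lists 3 genes are in the table.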

How the results depend on the processing

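Not among the alternatives fixed in advance were the fit without control 8 and LOY 5, the covariate, edgeR on recovered reads (which the fixed design named as an addition) and, for the Y-linked count and the gene lists with the X relatives, no filter, the mean of at least 50, array weights, the pseudocounts and, for the lists, removal of the Y-linked list. Quantile normalization, array weights, pseudocounts of 0.5 and 5 and a log2 fold change of at least 1 gave 2 genes, as in the main test. No filter, a mean of at least 50, leaving out control 8 with LOY 5, and edgeR each gave 0 genes, removal of the Y-linked list or the cardiomyocyte covariate 1, and DESeq2 303; with 1 library left out the count ran from 0 to 4. For Y-linked genes the count was 0 with no filter, with a mean of at least 50, without control 8 and LOY 5, and with edgeR, and 2 with DESeq2; with 1 library left out it was 0 or 1. Without a LOY library, also in the fit without control 8 and LOY 5, Acbd4 fell below the filter of 6 libraries and was not tested. The cause of the other changes was not tested. The log2 fold change of Ddx3y stayed between -9.37 and -8.23 with 1 library left out.

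The number of lists past the threshold was 1 with an estimated correlation, 1 with fry and 1 with the Y-linked list removed, and 1 to 4 with 1 library left out. In 6 of the fits with 1 library left out the Y-linked list was tested, at a camera adjusted p of 1.28e-09 to 3.65e-06. In the others Eif2s3y fell below the filter and the list could not be called. Its absence also changes the adjusted p of the other lists. The cardiomyocyte adjusted p was 0.406 with an estimated correlation, 0.466 with fry, and 3.97e-10 to 0.00118 with 1 library left out. The endothelial adjusted p was 0.0552 at a pseudocount of 0.5, 0.0610 without the Y-linked list, 0.406 with an estimated correlation, 0.482 with fry, and 0.000997 to 0.268 with 1 library left out. The fibroblast list passed with quantile normalization (0.0479), no filter (0.0121), array weights (0.0354) and without control 8 and LOY 5 (0.0435), and ran from 0.0271 to 0.390 with 1 library left out, passing without LOY 5, 14 or 15; it was 0.406 with an estimated correlation and 0.466 with fry. The list of X relatives stayed past no threshold, with a camera adjusted p of 0.131 to 0.813 with 1 library left out. Its member Zfx was called over all genes by DESeq2 (adjusted p = 0.00916).

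Directions turned only for genes and lists that passed in neither fit. For lists the direction is that of camera against all other genes, and the list mean kept its sign in part of these fits, such as glycolysis with no filter, interferon with array weights, and migration and dendritic cells without control 8 and LOY 5. Kdm5c was at -0.044 with a pseudocount of 5, -0.12 with the covariate, -0.043 with DESeq2 and -0.069 with edgeR, and Usp9x at 0.54 with array weights, 0.014 with a pseudocount of 0.5 and 1.60 without control 8 and LOY 5. With 1 library left out, log2 fold changes ran from -1.12 to 0.98 for Kdm5c, -0.22 to 1.72 for Kdm6a, -0.016 to 0.31 for Ddx3x, -1.06 to 0.78 for Usp9x and -0.87 to 0.16 for Uba1. Without control 8 and LOY 5 the direction turned for the lists of migration (adjusted p = 0.965), cytokines and NF-kB (0.928), interferon (0.240), mitochondrial genes (0.415) and dendritic cells (0.965); with array weights for interferon (0.988); with no filter for p53 (0.927) and glycolysis (0.998). Lists that turned with 1 library left out had adjusted p ranges of 0.637 to 0.991 (migration), 0.646 to 0.994 (oxidative burst), 0.255 to 0.980 (interferon), 0.469 to 0.991 (TGF-beta), 0.646 to 0.994 (apoptosis), 0.750 to 0.999 (glycolysis), 0.0340 to 0.980 (mitochondrial; past the threshold without LOY 15, in the direction of the main test), 0.539 to 0.991 (class I), 0.393 to 0.991 (macrophage) and 0.547 to 0.991 (dendritic).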

Other observations

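Chosen only after the result was seen were the split test of the DESeq2 count, its test on 124 genes, the count within the genotype of the higher mean and, for the cardiomyocyte list, the tests of carried-over RNA, of neutrophil share and of a single library; the naming of the abundant genes and of Gm47283 also followed their values. Among the most abundant transcripts of both genotypes were the ferritin genes Fth1 and Ftl1, which store iron, with 87958 ± 24868 and 82225 ± 16779 normalised reads in the control and 98255 ± 35629 and 87498 ± 34144 in the LOY libraries (SD, n = 6 each). The AP-1 genes Fos and Junb and the phosphatase gene Dusp1, which respond within minutes to stimulation or tissue handling, stood beside them, at log2 fold changes of 0.12 (SE 0.28), 0.27 (SE 0.31) and -0.31 (SE 0.35). Hcar2, a receptor for nicotinic acid, had 59054 ± 17655 in the control and 47298 ± 11055 in the LOY libraries (SD, n = 6 each). None of these passed the limma test.

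Gm47283, annotated near the distal end of chromosome Y (GRCm38, 90784738 to 90816464), was read in both genotypes, at 25.1 ± 28.1 normalised reads in the control and 52.3 ± 31.2 in the LOY libraries (SD, n = 6 each). Its log2 fold change was 1.41 (SE 1.29, limma adjusted p = 0.997). Whether its reads come from chromosome Y was not tested, so they do not show Y expression in the LOY libraries. Over the 194 tested genes of chromosome X the median log2 fold change was 0.14, and 4 of them had an unadjusted p below 0.05.

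The DESeq2 test on recovered reads, whose calls equal those of the authors' deposited table, gave 303 genes. Whether loss of Y set the genotypes apart in every library stays open for the 303 as a whole: 3.30% of them were fully separated, but 179 were above 0 in fewer than 6 libraries and had no way to be. Of the other 124, 10 (8.06%, 95% interval 3.94% to 14.3%) were fully separated, so most were not apart in every library. This does not argue against an effect of loss of Y on them. Eif2s3y, a Y-linked gene among the 303, was not fully separated either, with 0.828 normalised reads in control 7 and 16.8 in LOY 14. Chance is not excluded: 5 of 22 splits of the 12 libraries, the real one included, gave as many genes. The splits other than the real one gave 228 to 343. Reads in only some libraries, as few cells give, stay open too: called genes reached 10 normalised reads in a median of 2.0 fewer libraries than uncalled genes of the same mean, which a gene off in one genotype gives as well, and within the genotype of the higher mean the median was 1.0 fewer. Single genes of the 303, Ddx3y and Eif2s3y among them, can still be real, and the genotype remains an open source of any of them.

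The cardiomyocyte list mean was 1.94 log2 units higher in LOY. LOY 10 alone is argued against, since 71.4% of the difference was left without it. A lower share of neutrophil RNA stays open: the cardiomyocyte mean moved apart from the mean of the 8 other marker lists by 1.75, with a two-sided exact permutation p of 0.0519 (2.68 and 0.0238 against the macrophage, B cell and red cell lists alone, a choice made after the values were seen), and the endothelial, fibroblast and T and NK cell means stood higher in LOY while the other 5 stood lower. Chance is not excluded, as 50 of the assignments of the 12 libraries, the real one included, gave a difference as large (exact p = 0.0541) and the largest under any other split was 2.79. The list's genes went up and down together around their group means, over the 12 libraries pooled. The median correlation was 0.364 against a 95th percentile of 0.0769 over 10000 expression-matched lists. It was not computed for each genotype apart, and the list mean varied more in LOY (SD 2.01) than in control libraries (SD 0.73). Varying amounts of cardiomyocyte RNA carried into a sort for Ly6G would give such a correlation. The test cannot single out that source, since a list whose genes vary together for any reason passes it. The endothelial list passed it as well (0.154 against a 95th percentile of 0.130). Whether the LOY genotype changes that amount was not tested and stays open.

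For the 2 genes past the threshold in limma, 13 of 100 splits of the libraries, the real one included, gave as many, and the highest of the others gave 5, so chance is not excluded for the count. For the 3 lists past the threshold in camera, 27 of 100 splits, the real one included, gave as many, and the highest of the others gave 7. These counts do not bear on the Y-linked genes as a target named in advance, whose sums did not overlap between the genotypes.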
